A study of Escherichia coli with 6 samples.

How the data were processed

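The level of reporter repression was measured for a library of RyhB variants in 6 samples, at 21, 25, 29 and 33 °C with 1 sample each and at 37 °C with 2. Groups follow the labels. Cells were the ryhB deletion strain with the RyhB library and the reporter on plasmids, grown in a minimal medium with inducers for both. RyhB in the annotation used here (symbol ryhB, locus tag b4451, assembly ASM584v2) is 95 bases long, the length of the sequences in the table. Positions count from 1 at its 5′ end, and T stands for U.

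The authors sorted each culture into 6 gates of green over red fluorescence, regrew the cells, amplified the RyhB variants by PCR and sequenced them. Per the file headers, the gate bounds and the value given to each gate are a fluorescence signal (a ratio of green to red in instrument units), and Coverage is the ratio of reads passed to sorted cells. The deposited gate tables give the cells, the events and the reads that passed the filter in each gate in percent. For each variant the authors deposited the fraction of its cells in each gate, the log2 fluorescence, the log2 fold repression and an error. The deposited log2 fluorescence was checked to be the log2 of the gate values averaged with those fractions, within 0.00075. The fractions follow the gates' shares of events within 0.83 percentage points, while shares of sorted cells differ by up to 9.14 points at 21 °C. The deposited log2 fold repression equals a constant of each sample minus the log2 fluorescence. The constants were 15.57, 16.26, 16.19, 16.55, 16.19 and 16.40 from 21 °C to 37 °C replicate 2, and their origin is not given in the sources used here. The deposited error follows a floor of 0.022 log2 units plus a term for the number of cells.

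The series table held 81522 lines and 76534 distinct sequences, of which 4414 stood on more than 1 line. Lines with the same sequence were pooled by cells. The wild type stood on 14 lines, the first with at least 95.1% of its cells. There were 70688 sequences with 1 to 6 differences from the wild type, 5845 with more, and 15 with other letters, which were left out. The cell column of every per-sample table was identical to that of 37 °C replicate 2, so cells were taken from the series table, where each sample has its own.

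Sorted cells were 7462715, 9082727, 6310936, 5211535, 7264791 and 6547762 from 21 °C to 37 °C replicate 2, and reads passed 17781437, 21888606, 15089439, 12351245, 16999779 and 17367309, or 2.34 to 2.65 reads per cell. Single substitutions, and double substitutions at pairs or with A31G, entered with at least 20 cells in each of the 6 samples, which removed A62C. Double substitutions with at least 20 cells numbered 12725 to 14460 per sample. The level was the deposited log2 fluorescence, and the cost was the level minus that of the wild type in the same sample. All costs of a sample thus share 1 wild-type value. The repression span was the median level of variants with 3 or more substitutions at positions 38 to 46 minus the wild type. The slope per substitution was fitted over 0 to 6 substitutions. The span, this slope and additive regression used every variant with at least 20 cells in the sample at hand. Their variants therefore differed between samples (29 to 42 for the span).

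Mean effects and temperature slopes of single substitutions came from 1 limma 3.58.1 fit (R 4.3.3) with equal weights and temperature centred on its mean, with Benjamini-Hochberg adjustment at 0.05 over 281 substitutions. Named are the 10 largest losses and 5 largest gains past the threshold with the same sign in every sample, up to 10 steepest slopes in each direction past it, and the 10 positions with the largest mean cost. T46A, A69T, T87A and the other 5′ positions were named after their values were seen. Region means were tested against 0 by exact sign-flip permutation (smallest p = 0.031) and trends by exact permutation of the temperatures (smallest p = 0.0028), all two-sided, with Benjamini-Hochberg adjustment over the 5 whole-library measures, the 8 regions, the 3 measures by base or the 2 units of terminator pairs. Regions were the 5′ segment (2 to 31), linker (32 to 37), pairing core (38 to 46), segment after the core (47 to 58), AU-rich segment (59 to 68), terminator stem (69 to 75 and 81 to 87), loop (76 to 80) and U tail (88 to 90). Positions 91 to 95 entered the counts of substitutions but no region. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 did the rest, and ViennaRNA 2.7.2 predicted folds.

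The slope fit was tested on simulated data of 281 substitutions with a noise SD of 0.03 log2 units. It recovered 32.4% of slopes of 0.004 log2 units per °C and 100% of slopes of 0.01 and 0.02, with 1 false call among 181 unchanged substitutions. The noise was independent and had the spread between the 37 °C samples. Residual SDs of named substitutions in the real fit went from 0.03 (C54A) to 0.20 (G44C), and all costs of a sample share 1 wild-type value. These rates therefore do not carry over to the real fit, in which C47A, with a slope of -0.011, did not pass. Regions, tests, thresholds and naming rules were fixed before the data were examined. Alternatives fixed then were cell minimums of 5 and 50, the mean log2 gate centre, the median gate, leaving out each sample, the library median as reference, scaling by the span, additive regression, another disrupted level, weights from the errors, and the contrast of 37 °C with 21, 25 and 29 °C. Added after seeing the data were the line with most cells per sequence, scaling by the deposited wild-type fold repression, a higher cell minimum, shares of the span combined with other settings, a longer U tail, pairs of the 5′ segment, comparisons within pairs and the core by base without T46.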

Results

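RyhB is a small regulatory RNA of Escherichia coli that is made when iron is short and represses target messenger RNAs by base pairing, with the help of the RNA chaperone Hfq. The samples were a pooled library of RyhB sequence variants carried on a plasmid in a strain without the chromosomal ryhB gene, together with a plasmid that carried a green fluorescent target reporter. The labels name no target. Cells were sorted by the ratio of green to red fluorescence into 6 gates and the RyhB variants in each gate were sequenced, a design called sort-seq. Cultures had been grown at 21, 25, 29 and 33 °C (1 sample each) and at 37 °C (2 samples). The series title names the question as how temperature affects the specificity and the efficiency of the RNA. Only 37 °C was replicated, and the labels give no separate cultures for the 2 samples. The p-values of trends and of limma therefore measure the spread around a trend with temperature. Sign-flip p-values measure whether the sign of a mean repeats over the 6 samples, which hold the same variants.

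Between 5211535 and 9082727 cells were sorted per sample, and 12351245 to 21888606 reads per sample passed the authors' filter. The wild-type sequence made up 17.3% to 22.6% of the cells. The table listed 282 single substitutions, at every position from 2 to 95, and the median single substitution was carried by 3258 to 5472 cells per sample. In all 6 samples, 281 of them reached the minimum of 20 cells, and A62C did not. Substitutions are written as the wild-type base, the position counted from 1 at the 5′ end of RyhB, and the new base, with T for U. The cost of a substitution is its log2 fluorescence minus that of the wild type in the same sample, so that a positive cost is a loss of repression and a negative cost a gain. The deposited counting error of a median single substitution was 0.02 to 0.03 on the log2 scale, a fixed floor plus a term for the number of cells.

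Wild-type RyhB repressed the reporter more strongly at higher growth temperature. Its log2 fold repression, as the authors deposited it, was 0.72 at 21 °C, 0.91 at 25 °C, 1.00 at 29 °C, 1.12 at 33 °C and 1.16 ± 0.03 at 37 °C (SD, n = 2), which is 1.65-fold at 21 °C and 2.20-fold and 2.27-fold in the samples of 37 °C. The repression span, the median level of variants with 3 or more substitutions in the pairing core (positions 38 to 46) minus the wild-type level, widened from 0.65 at 21 °C to 1.19 ± 0.02 at 37 °C (SD, n = 2) on the log2 scale, over 29 to 42 such variants per sample. In log2 units, a straight line of the level on the number of substitutions (0 to 6) was also steeper in the warm. It rose by 0.08 log2 units per substitution at 21 °C and by 0.14 ± 0.0015 (SD, n = 2) at 37 °C. This was not a larger loss at the first step. Median log2 fold repression with 1 substitution was 0.51 at 21 °C, against 0.72 for the wild type. In the samples of 37 °C it was 0.91 and 0.93, against 1.14 and 1.19. With 3 substitutions it was already down to 0.15 at 21 °C and to 0.16 and 0.21 at 37 °C. From 21 °C to the mean of 37 °C the slope per substitution grew 1.78-fold, the span 1.84-fold and the deposited log2 fold repression 1.61-fold. The slope thus did not outgrow the span but outgrew the deposited fold repression.

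All 3 quantities followed temperature over the 6 samples. For the fold repression, r was 0.97 (exact permutation p = 0.0028, two-sided, adjusted over 5 whole-library measures p = 0.0046) and rho was 0.99 (exact permutation p = 0.0056, adjusted p = 0.0093). For the span, r was 0.99 and rho 0.99, and for the slope per substitution r was 0.98 and rho 0.99, with the same exact permutation p-values, of which 0.0028 is the smallest these permutations can give. Without the 2 samples farthest from the median temperature, r stayed between 0.94 and 0.99 for the fold repression, between 0.996 and 0.999 for the span and between 0.97 and 0.98 for the slope. The samples at 25 °C and 37 °C are equally far from that median, so each was left out in turn together with 21 °C. The wild-type fluorescence itself had no such relation (r = 0.32, exact permutation p = 0.53, rho = 0.20, exact permutation p = 0.70), and its r became -0.49 without the 21 °C sample. The fluorescence of core-disrupted variants rose from 15.50 to 16.32 ± 0.13 (SD, n = 2) on the log2 scale (r = 0.79, exact permutation p = 0.031, adjusted p = 0.038), but rho was 0.75 (exact permutation p = 0.11) and r was 0.32 to 0.78 without the 2 farthest samples. Fluorescence was in instrument units of each sort, whereas the span compares variants within a sort.

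**Figure D1:**
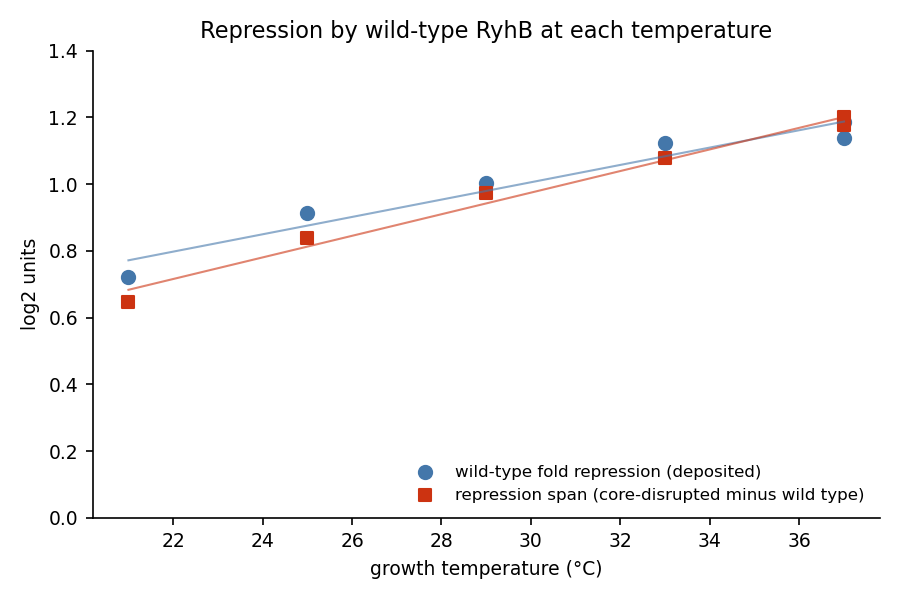
Repression by wild-type RyhB (log2 units, y axis) against growth temperature (°C, x axis), with 1 point per sample and straight lines of least squares: circles are the deposited wild-type fold repression and squares the repression span. The span goes from 0.65 at 21 °C to 1.18 and 1.20 in the samples of 37 °C.

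Most single substitutions weakened repression, and those of the pairing core and the terminator stem did so most. With limma and Benjamini-Hochberg adjustment at 0.05, 209 of 281 substitutions lost repression and 44 gained it in the mean over the 6 samples, and 28 did not pass. The sign was the same in every sample for 198 of the 209 and for 35 of the 44. Additive regression over variants with 1 to 6 substitutions called 19 gains. The 10 largest losses were A31G in the 5′ segment, C40G, C40T, T42G and T43A in the pairing core, and C72A, C82A, G84T, G85A and G85T in the terminator stem. A31G had a mean cost of 1.13 ± 0.02 (SE), C40G of 1.06 ± 0.03 (SE) and G84T of 1.02 ± 0.02 (SE), with limma adjusted p-values of 5.7e-09, 8.6e-09 and 4.0e-09. The other 7 cost between 0.99 and 1.01. The 5 largest gains were C47A at -0.48 ± 0.03, G53T at -0.46 ± 0.02, C54G at -0.44 ± 0.02 and G53A at -0.42 ± 0.02 in the segment after the core, and T63G at -0.45 ± 0.02 in the AU-rich segment (SE throughout). Their limma adjusted p-values lay between 1.6e-07 and 1.1e-06.

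By position, averaged over the 3 substitutions, C40 of the core was the most sensitive at 1.02 ± 0.18 (SD over 6 samples). Next came G84 and G85 (both 1.00) and G74 (0.97) in the terminator stem and T42 (0.98), C45 (0.93), T43 (0.92) and G38 (0.91) in the core. G70 of the terminator stem (0.90) and G8 of the 5′ segment (0.89) completed the first 10 positions. In the 5′ segment the position means were highest at 2, 5 to 9, 21 to 22 and 27 to 31, from 0.28 to 0.89, and 0.25 at position 15, while positions 10 to 14 and 16 to 20 lay between -0.04 and 0.08. At the outermost terminator pair, A69 and T87 each had a mean cost of 0.01.

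**Figure D2:**
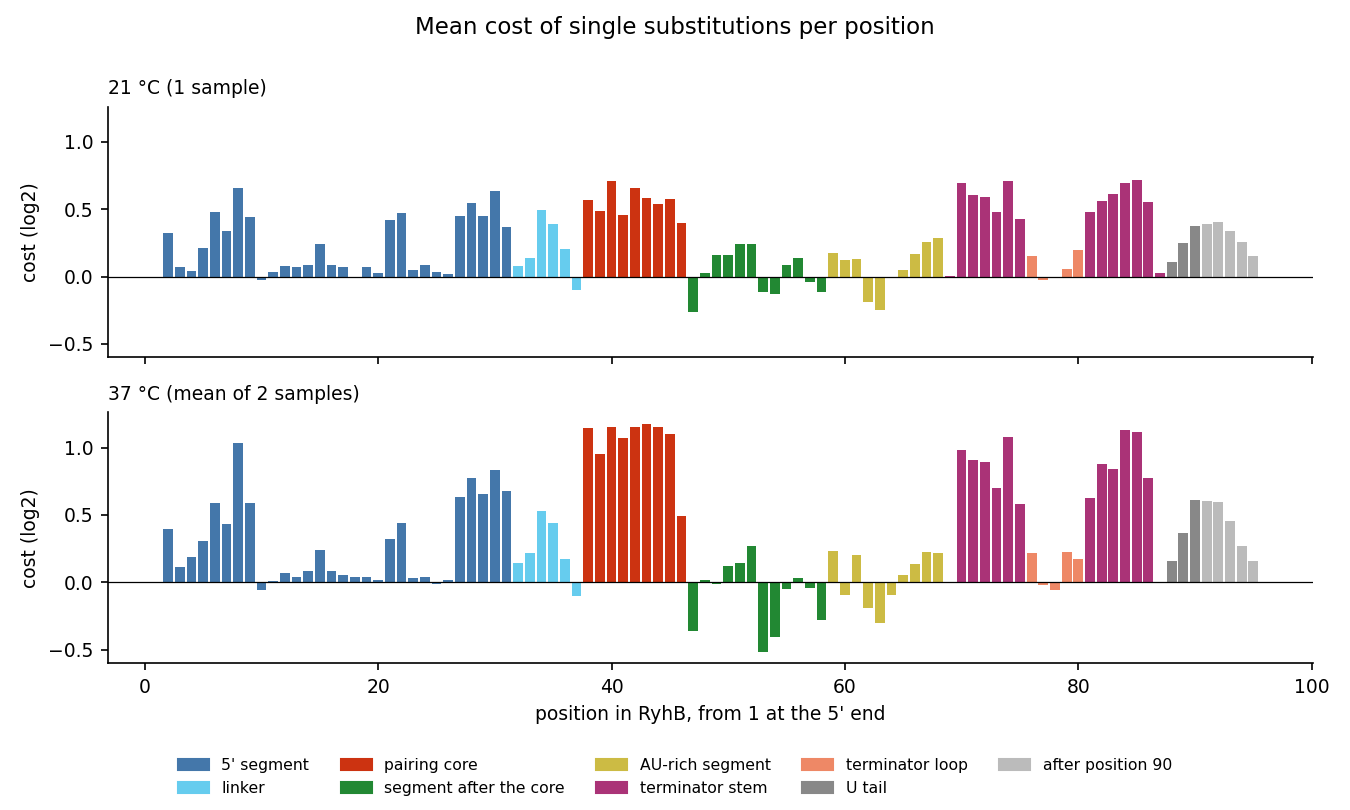
Mean cost of single substitutions (log2, y axis) at each RyhB position (x axis, from 1 at the 5′ end), at 21 °C (1 sample, upper panel) and 37 °C (mean of 2 samples, lower panel), coloured by region. Position 40 of the core stands at 0.71 at 21 °C and at 1.15 and 1.16 in the samples of 37 °C.

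The regions had been fixed on the mature RNA before the data were examined. The pairing core, which holds the bases RyhB is known to pair with its targets, had the largest mean cost of the 8 regions, 0.84 ± 0.21 (SD over 6 samples), and each of its 27 substitutions lost repression. With additive regression the core and the terminator stem both averaged 0.46. Its mildest was T46A at 0.23 ± 0.01 (SE). The terminator stem, the hairpin at which transcription ends and part of the Hfq-binding 3′ end, followed at 0.69 ± 0.10, with 39 of 42 substitutions losing repression and 2, A69T and T87A, gaining it. The U tail at positions 88 to 90 averaged 0.36 ± 0.06 with losses in 9 of 9. The 5′ segment averaged 0.27 ± 0.02, with 66 losses and 6 gains among 90. The linker averaged 0.22 ± 0.02 with 13 losses and 2 gains among 18. The terminator loop averaged 0.10 ± 0.02 with 8 losses and 6 gains among 15, and the AU-rich segment 0.08 ± 0.03 with 18 losses and 9 gains among 29. The segment after the core was the one region with more gains, 19, than losses, 14, among 36, and its mean of -0.04 ± 0.06 did not differ from 0 (exact sign-flip p = 0.16, adjusted p = 0.16), but with additive regression it was 0.06 and passed as a loss (exact sign-flip adjusted p = 0.031). The other 7 regions were above 0 in 6 of 6 samples (exact sign-flip p = 0.031, the smallest that 6 samples allow, adjusted over 8 regions p = 0.036). Relative to the library median in place of the wild type, the means of all regions but the core fell below 0.

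The cost of many core substitutions grew with temperature, and the cost of 16 of 36 substitutions after the core fell. In the limma slope over the 6 samples, 97 substitutions had a cost that rose with temperature and 31 a cost that fell, out of 281, at an adjusted p of 0.05. Of the 97, 25 were in the core (of 27 measured), 26 in the terminator stem (of 42) and 27 in the 5′ segment (of 90). Of the 31, 16 were in the segment after the core (of 36) and 7 in the AU-rich segment (of 29). As shares of the span in each sample, the split turned: 15 substitutions rose and 140 fell, so that rises went from 75.8% of the calls in log2 units to 9.68% of the calls as shares. Of the 97 that rose in log2 units, 11 also rose as a share and 49 fell as a share. Scaled by the deposited wild-type fold repression instead, an alternative added after seeing the data, 22 of them also rose and 12 fell. By region as shares of the span, 5 rose and 6 fell in the core, 0 and 34 in the terminator stem, 2 and 41 in the 5′ segment and 3 and 20 in the segment after the core. Relative to the library median, 17 rose and 228 fell. That reference lowers every cost of a sample by the same amount, so that the core averaged 0.0036 relative to it. The amount grew with temperature, which by itself turns slopes down together, so these counts do not speak to single substitutions. With the mean log2 gate centre as the level the log2 counts were 36 and 18, with the median gate 57 and 25, without replicate 2 of 37 °C 63 and 20, and without the 25 °C sample 75 and 20. The contrast of 37 °C with 21, 25 and 29 °C, on 5 samples, called 16 and 9.

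The 10 steepest rises were G38C, A39C, A39T, A41C, A41T, T42A, T43C, G44A and G44C in the core and A31G in the 5′ segment. G44C went from a cost of 0.34 at 21 °C to 1.09 at 37 °C, a slope of 0.056 ± 0.010 (SE) log2 units per °C (limma adjusted p = 0.0053). A41T went from 0.36 to 1.21 with a slope of 0.055 ± 0.0043 (SE, limma adjusted p = 0.00015), and T43C from 0.45 to 1.18 with a slope of 0.053 ± 0.0080 (SE, limma adjusted p = 0.0020). A31G went from 0.74 to 1.53 and 1.47 in the samples of 37 °C with a slope of 0.050 ± 0.0042 (SE, limma adjusted p = 0.00016). The other 6 had slopes of 0.036 to 0.044. As shares of the span, A41T rose from 55.2% at 21 °C to 101.8% at 37 °C. Over the same range G44C went from 52.8% to 91.6% and T43C from 69.2% to 99.7%. G38C rose from 68.3% to 97.7% and 98.3% in the samples of 37 °C, and A41C from 90.9% to 105.5%. Each of these passed the adjusted threshold, whereas A31G, A39C, A39T, T42A and G44A did not pass as shares. The rise was not steady for G44C, at 20.7% at 25 °C and 33.4% at 29 °C, or for T43C, at 51.0% and 50.9%. G44C rests on 119 to 443 cells per sample. Its costs in log2 units were 1.15, 1.03, 0.74, 0.34, 0.32 and 0.17 from the sample with the narrowest gate 4 (upper over lower bound) to the widest. Gate width and temperature thus cannot be told apart for G44C. A41T differed in that its cost rose at each step of temperature, from 0.36 over 0.54, 0.61 and 0.94 to 1.21.

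The 10 steepest falls were C49A, T51C, G53A, G53C, G53T, C54A, C54T, T55C and C58G in the segment after the core and G60A in the AU-rich segment. G53T went from -0.18 at 21 °C to -0.64 at 37 °C, a slope of -0.032 ± 0.0041 (SE) log2 units per °C (limma adjusted p = 0.0011). C54T went from -0.05 to -0.42 with a slope of -0.026 ± 0.0033 (SE, limma adjusted p = 0.0011). T55C went from 0.04 to -0.30, with a slope of -0.024 ± 0.0026 (SE, limma adjusted p = 0.00052). T51C, which lost repression at 21 °C (0.31), stood at 0.01 at 37 °C. The other 6 had slopes of -0.016 to -0.023. G53C did not pass without the 21 °C sample (limma adjusted p = 0.079), T51C with the mean log2 gate centre (limma adjusted p = 0.079), or C58G and C49A with additive regression (slopes of -0.0027 and -0.0045, limma adjusted p = 0.34 and 0.054). All 10 also fell as shares of the span.

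Regions moved apart with temperature. The core cost rose from 0.55 at 21 °C to 1.04 ± 0.01 (SD, n = 2) at 37 °C on the log2 scale (r = 0.99, exact permutation p = 0.0028, adjusted over 8 regions p = 0.0074, rho = 0.99, exact permutation p = 0.0056, adjusted p = 0.015), and r was 0.97 to 0.99 without the 2 farthest samples. The terminator stem rose from 0.51 to 0.75 ± 0.02 (r = 0.90, exact permutation p = 0.0083, adjusted p = 0.017, rho = 0.90, exact permutation p = 0.028, adjusted p = 0.056), with r of 0.58 to 0.94 without the 2 farthest samples. The 5′ segment rose from 0.23 to 0.29 ± 0.01 (r = 0.96, exact permutation p = 0.0028, adjusted p = 0.0074, rho = 0.99, exact permutation p = 0.0056). The segment after the core fell from 0.03 to -0.09 ± 0.01 (r = -0.97, exact permutation p = 0.0028, adjusted p = 0.0074, rho = -0.99, exact permutation p = 0.0056). The linker (r = 0.83), terminator loop (r = 0.85), U tail (r = 0.78) and AU-rich segment (r = -0.78) did not pass, with exact permutation adjusted p-values of 0.051, 0.051, 0.051 and 0.069. The terminator stem trend was lost with the mean log2 gate centre (exact permutation adjusted p = 0.20) and the median gate (adjusted p = 0.12), and so was the 5′ segment trend (adjusted p = 0.21 and 0.12). The terminator stem trend also did not pass in 4 of 6 leave-outs (exact permutation adjusted p = 0.067 to 0.10), the 5′ segment trend without 21 °C (adjusted p = 0.067), and that of the segment after the core without 33 °C or with additive regression (adjusted p = 0.067 each).

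As shares of the span, the core took 85.3% at 21 °C and 87.9% ± 0.74 (SD, n = 2) at 37 °C, with no trend that passed (r = 0.59, exact permutation p = 0.23, rho = 0.64, exact permutation p = 0.20). Scaled by the deposited wild-type fold repression, an alternative added after seeing the data, the core trend passed (r = 0.918, exact permutation adjusted p = 0.036). Core-disrupted variants had a deposited log2 fold repression of 0.08 at 21 °C and of -0.04 and -0.01 in the samples of 37 °C. The span was therefore smaller than the fold repression at 21 °C and larger at 37 °C, which raises shares of the span in the cold relative to the warm. The terminator stem fell from 78.9% to 63.1% ± 1.09 of the span (r = -0.97, exact permutation p = 0.0056, adjusted p = 0.011, rho = -0.99, exact permutation p = 0.0056). Scaled by the fold repression, the stem also fell (r = -0.87, exact permutation adjusted p = 0.041). The 5′ segment fell from 35.2% to 24.3% ± 0.81 (r = -0.95, exact permutation adjusted p = 0.011) and the linker fell by 11.3 points to 19.7% ± 1.08 (r = -0.94, exact permutation adjusted p = 0.011). The segment after the core fell from 4.90% to -7.56% ± 0.87 (r = -0.96, exact permutation adjusted p = 0.011), and the AU-rich segment from 12.8% to 3.93% ± 0.60 (r = -0.95, exact permutation adjusted p = 0.013). The direction of the terminator stem, 5′ segment and linker trends thus depended on the unit, while that of the segment after the core did not.

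**Figure D3:**
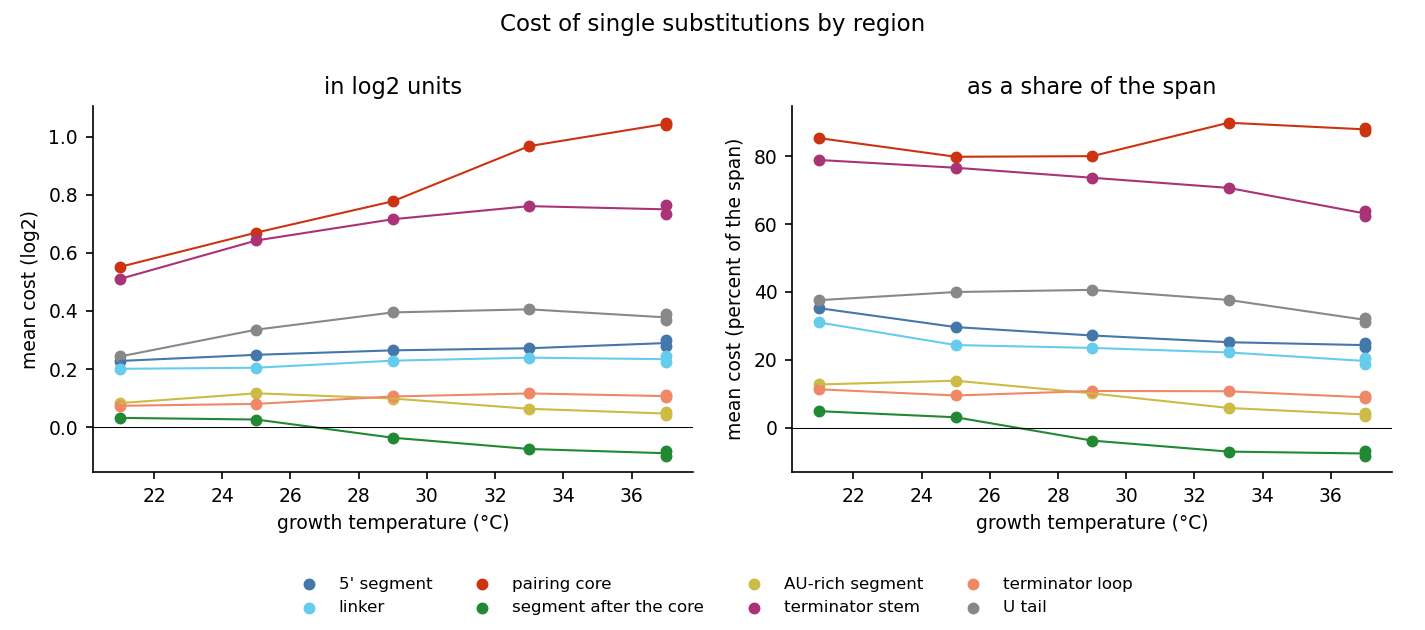
Mean cost of single substitutions of each region against growth temperature (°C, x axis), in log2 units (left) and as a percentage of the repression span of the same sample (right), with 1 point per sample and lines through the means per temperature. On the right the pairing core lies at 85.3% at 21 °C and 87.9% at 37 °C, and the terminator stem goes from 78.9% to 63.1%.

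Core substitutions were also compared by the base replaced, since a lost G-C pair costs more pairing energy than a lost A-U pair. Substitutions at G or C cost 0.93 ± 0.23 and those at A or U 0.77 ± 0.19 (SD over 6 samples), a difference of 0.15 ± 0.04 that was above 0 in 6 of 6 samples. Without T46, at the end of the core, a choice made after seeing the data, A or U cost 0.86 ± 0.23 and the difference was 0.07 ± 0.02. The lowest A or U costs then left were A39G at 0.49 and A41G at 0.59, and the lowest at G or C was G44C at 0.63. The difference was not tested against this spread among substitutions, so it cannot be read as an effect of pairing energy. Costs at G or C and at A or U both rose with temperature (r = 0.99 each, exact permutation p = 0.0028, adjusted over 3 measures p = 0.0042, rho = 0.99 each, exact permutation p = 0.0056). The difference went from 0.08 at 21 °C to 0.17 ± 0.01 (SD, n = 2) at 37 °C (r = 0.82, exact permutation p = 0.036, adjusted p = 0.036), but rho was 0.52 (exact permutation p = 0.30), and r was -0.39 to 0.73 without the 2 farthest samples, so this relation rests on them. As a share of the span it had no trend that passed (r = 0.24, exact permutation p = 0.64).

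Pairs of the terminator stem could be restored by a second substitution. At 6 of the 7 pairs (all but 69 with 87), 10 double substitutions kept a Watson-Crick or G-U pair and 13 broke it, with at least 20 cells in each sample. Kept pairs cost 0.27 ± 0.08 and broken pairs 0.87 ± 0.13 (SD over 6 samples). G74T alone cost 0.98 and C82A alone 1.01, and together they cost 0.14 ± 0.16 (SD over 6 samples). A73T and T83G, which together form a U-G pair, cost 0.85 and 0.83 alone and 0.15 ± 0.10 together. C72A with G84T was the least restored, at 0.70 ± 0.14. The kept doubles rest on few cells, 20.8 to 217.7 in the sample with the fewest, and the broken ones on 20.0 to 271.3. Relative to the sum of the single costs, kept pairs lay below broken pairs by a mean of 0.52 log2 units: kept minus broken was -0.52 ± 0.06 (SD over 6 samples), below 0 in 6 of 6 samples (exact sign-flip p = 0.031, the smallest possible). A cell minimum 10 times higher left 1 kept and 1 broken double, at different pairs, with a difference of -0.78. Its trend with temperature did not pass by r (r = -0.71, exact permutation p = 0.12) and passed by rho (rho = -0.87, exact permutation p = 0.033, adjusted over 2 units p = 0.044). As a share of the span it shrank from -76.3% at 21 °C to -47.9% ± 2.78 (SD, n = 2) at 37 °C (r = 0.79, exact permutation p = 0.031, adjusted p = 0.061), and without the 2 farthest samples r was 0.38 to 0.73.

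**Figure D4:**
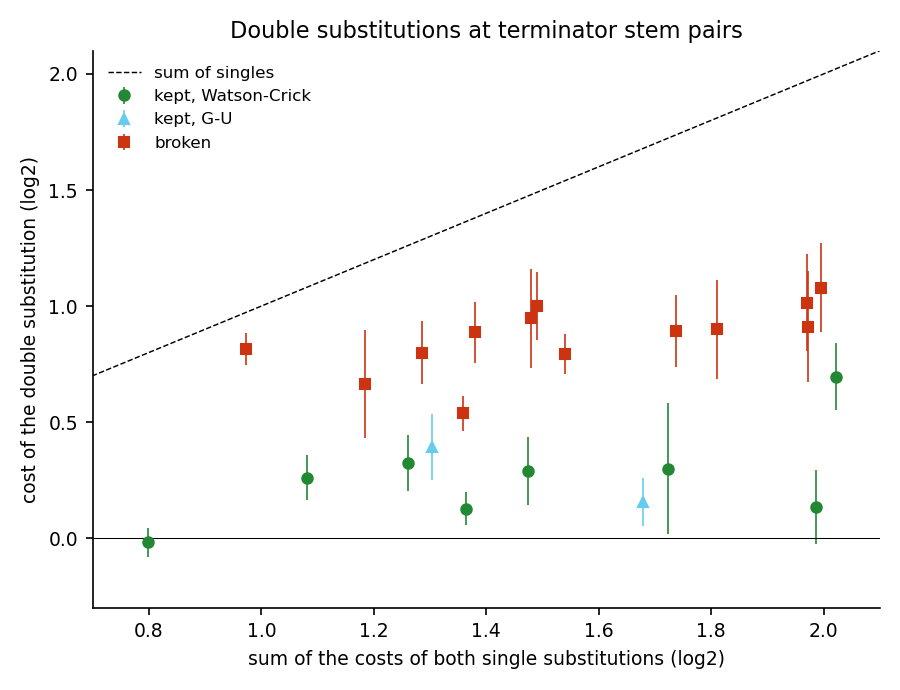
Cost of double substitutions at terminator stem pairs (log2, y axis; mean of 6 samples, bars are SD) against the sum of the costs of both single substitutions (log2, x axis), for pairs kept as Watson-Crick (circles), kept as G-U (triangles) or broken (squares), with the dashed line at the sum. Kept pairs average 0.27 and broken pairs 0.87.

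The 37 °C samples gave nearly the same costs. Across the 281 single substitutions, which are not independent replicates, r was 0.997 and rho 0.996, and the difference between both samples had an SD of 0.04 log2 units, or 3.14% of the span. Costs at 33 °C correlated with those at 37 °C with r of 0.989 and 0.993, and costs at 21 °C with r of 0.932 and 0.940.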

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

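The sign comparison of substitutions between temperatures and the analysis of deletions were chosen after the data were seen. G60A drew attention because its cost was positive in the cold samples and negative in the warm ones: the mean was 0.14 at 21, 25 and 29 °C and -0.06 at 33 and 37 °C, with a slope of -0.0192 log2 units per °C (limma adjusted p = 0.00060). T61C did the same, with means of 0.08 and -0.02 and a slope of -0.00868 (limma adjusted p = 0.00995).

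The table also held 36 sequences that read as the loss of a single base, with at least 20 cells in every sample and more than 6 differences from the wild type, which the comparisons of substitutions do not use. Their mean cost was 0.26 at positions 1 to 31 (16 deletions), 0.56 at 32 to 37 (1 deletion), 0.94 at 38 to 46 (3 deletions) and 0.55 at 69 to 87 (7 deletions). At positions 47 to 68 it was -0.18 (9 deletions, 5 below 0 and 1 above 0 in all 6 samples).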

How the results depend on the processing

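Scaling by the wild-type fold repression, the higher cell minimum and the shares under other settings were chosen after the data were seen. Of 471 summary values under other settings, 334 kept direction and side of the threshold, 76 were weaker, 11 stronger, 27 reversed and 23 counts moved; of 557 values of named substitutions 546 were kept, 11 were weaker and none reversed. Some outcomes of the summary values were fixed in advance. Sign-flip means that passed on all samples were bound to count as weaker in leave-outs, since 5 samples allow no p below 0.0625. The library median cancels in the base difference and the terminator pairs, so these were bound to be kept under it. The counts therefore cannot be read as a rate of robustness. Trends of the span and slope per substitution kept direction and threshold under the settings run for them. The trend of the fold repression kept both when samples were left out, the only alternative run for it. Where no cause is given below, the cause was not tested. Depth limits doubles more than singles. No paired analysis was possible because no sample shares a number across temperatures.

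Relative to the library median, which lowers every cost of a sample alike, region means were -0.57 (5′ segment), -0.62 (linker), 0.0036 (core), -0.88 (after the core), -0.76 (AU-rich), -0.15 (stem), -0.74 (loop) and -0.48 (U tail), trends had r of -0.934 (5′), -0.946 (linker), 0.748 (core), -0.978 (AU-rich), -0.962 (stem), -0.952 (loop), -0.982 (U tail) and 0.560 (core A or U), losses were 36, gains 229, rises 17 and falls 228. Scaled by the span, r was -0.948 (5′), -0.937 (linker), 0.590 (core), -0.955 (AU-rich), -0.970 (stem), -0.659 (loop), -0.735 (U tail), 0.666 (core G or C), 0.500 (core A or U), 0.236 (their difference) and 0.786 (terminator pairs), with 15 rises and 140 falls. Scaled by the wild-type fold repression, r was -0.887 (5′), -0.895 (linker), -0.939 (AU-rich), -0.874 (stem), -0.223 (loop), -0.366 (U tail), 0.502 (base difference), 0.653 (terminator pairs) and, past the threshold, 0.918 (core), 0.949 (core G or C) and 0.869 (core A or U), with 24 rises and 87 falls.

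With the mean log2 gate centre r was 0.630 (5′), 0.685 (stem) and 0.660 (base difference), with 36 rises and 18 falls; with the median gate 0.814, 0.778 and 0.663, with 57 rises. Additive regression gave r of 0.914 (linker), -0.785 (after the core), 0.069 (AU-rich), 0.773 (loop) and 0.899 (U tail), a mean of 0.061 after the core, 19 gains and 17 falls, and as shares 9 rises. The higher cell minimum gave 0.601 (base difference), 0.911 (loop) and 0.176 (terminator pairs, with a mean of -0.78, from 1 kept and 1 broken double). The contrast of 37 °C with 21, 25 and 29 °C gave 16 rises and 9 falls.

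Leaving out 1 sample, r ranged from -0.490 to 0.578 (wild-type fluorescence), 0.601 to 0.885 (base difference), 0.922 to 0.985 (5′), 0.703 to 0.971 (linker), -0.985 to -0.959 (after the core), -0.986 to -0.698 (AU-rich), 0.856 to 0.935 (stem), 0.710 to 0.915 (loop) and 0.472 to 0.856 (U tail). Means ranged from 0.26 to 0.27 (5′), 0.22 to 0.23 (linker), 0.80 to 0.90 (core), 0.067 to 0.082 (AU-rich), 0.67 to 0.72 (stem), 0.094 to 0.103 (loop), 0.35 to 0.38 (U tail) and -0.56 to -0.50 (terminator pairs); 5 samples allow no exact sign-flip p below 0.0625. Rises ranged from 63 to 104, falls from 20 to 34, and as shares from 8 to 30 and 111 to 143.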

Other observations

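Of the 13 tests of this part, those on the order of the temperatures, the span, cell numbers, the level definition, gate widths and the A31G partners, the comparisons within pairs, and the comparison of transitions with transversions, were chosen after the result was seen. The tests of pairs were written before their values, but the pairs themselves came from costs already seen.

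Doubles in the 5′ segment behaved like pairs of a stem. Double substitutions were looked for at 5 with 31, 6 with 30, 7 with 29, 8 with 28 and 9 with 27. None passed the cell minimum at 9 with 27, and 6 with 30 had a single one, which broke the pair. The 5 that kept a pair, all at 5 with 31, 7 with 29 or 8 with 28, cost 0.16 on average and the 7 that broke it 0.64. Relative to the sum of the single costs, kept minus broken was -0.58 ± 0.07 (SD over 6 samples), from -0.67 to -0.48, below 0 in 6 of 6 samples (exact sign-flip p = 0.031). G8T and C28A cost 0.87 each alone and 0.37 together. Within pairs the difference was -0.83 at 8 with 28, -0.46 at 7 with 29 and -0.18 at 5 with 31 (mean -0.49, exact permutation p = 0.033 over doubles within pairs). The last rests on 1 kept double, whose value at 33 °C lay above those of both broken ones, and 8 with 28 has 1 broken double. At 7 with 29, the broken A7C with T29A (-0.84) lay below the kept A7G with T29C (-0.50) in 6 of 6 samples. Apart from this exception the values are consistent with base pairs of 7 with 29 and 8 with 28 that repression needs. Pairs of 5 with 31, 6 with 30 and 9 with 27 stay open, and whether they act through RNA stability or Hfq was not tested.

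A31G, the costliest substitution in the mean over samples and at 33 and 37 °C, lost much of its cost with most partners at positions 53 to 59 and with some at 32 and 33. Among partners that cost under 0.5 alone, leaving out positions 28 to 35, doubles with 11 partners at 53 to 60 had a median cost of 0.28 and those with 79 partners elsewhere 1.09, and 9 of 11 against 0 of 79 cost less than 0.5. At position 60, the doubles with G60A (0.88) and G60T (0.68) stayed more costly. At positions 28 to 35, left out of that test, doubles cost 0.04 with A32T, 0.46 with A33T, 0.68 with A32G, 1.04 with T29C and 1.08 with C35T. Doubles with C28A (1.08), G30T (0.80), G34A (0.69) and A59G (1.14) say little, since these cost 0.87, 0.79, 0.50 and 0.72 alone. Relative to the sum of the single costs the medians differed by -0.50 (permutation p = 1.0e-05, the smallest the draws allow). A helix of positions 28 to 35 with 53 to 60, in which A31G turns an A-C mismatch at 31 and 57 into a G-C pair, is a possible explanation. C54T, C57T and C58T, which could keep a G-U pair, gave doubles of 0.28, 0.27 and 0.36, so the loss was not limited to partners that break a pair, and the helix stays open. In the wild type, doubles that kept another pair of that helix (7) cost more, relative to the sum, than doubles that broke it (10), by 0.11 (0.06 to 0.18, above 0 in 6 of 6 samples, exact sign-flip p = 0.031; without pair 29 with 59, 0.099). The 6 samples measure the same doubles, however, and within the 5 pairs with both kinds the difference was from -0.006 to 0.23 (exact permutation p = 0.34 over doubles within pairs), so a helix in the wild type stays open.

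Transitions cost less on average than transversions in every sample in 6 of 9 groups of positions, which were the regions and positions 91 to 95. In each of these 6 groups the difference was below 0 in 6 of 6 samples (exact sign-flip p = 0.031, adjusted over 9 groups p = 0.047). The difference was -0.35 ± 0.05 (SD over 6 samples) in the U tail, -0.22 ± 0.04 in the terminator stem, -0.14 ± 0.02 at positions 91 to 95, -0.08 ± 0.01 in the 5′ segment, -0.07 ± 0.01 in the linker and -0.02 ± 0.01 in the terminator loop. The difference did not pass in the core (-0.05 ± 0.03, 5 of 6, exact sign-flip p = 0.062), after the core (0.03 ± 0.02, exact sign-flip p = 0.062) and in the AU-rich segment (0.01 ± 0.02, exact sign-flip p = 0.22). All 6 samples hold the same substitutions, so these p-values measure only whether the sign repeats. The difference was not tested against the spread among substitutions. The U tail had 3 transitions and 6 transversions. In the terminator loop, single costs ranged from -0.14 to 0.57, against a difference of -0.02.

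Costs in log2 units rose with temperature more often than they fell. Of 100 orders of the temperatures, the real one included, 1 gave as many slopes past the threshold, the real order with 128. The highest other gave 120, under an order that correlated with the real one at r = 0.925. This argues against chance for the number of slopes but does not exclude it. Only 100 of 360 distinct orders were drawn, and all costs of a sample share 1 wild-type value. Such orders also cannot separate temperature from other differences between sorts that changed with it. The balance of rises and falls was not tested by these orders, and it turned with the reference and the scaling. Cell numbers argue against a counting effect, since slope size and mean cells had rho = -0.024 across substitutions (permutation p = 0.69). A wider span at higher temperature may account for the rise and stays open: 11.34% of the rising substitutions also rose as a share of the span, between the bound of 10% under which the span would account for the rise and the bound of a share above 1 in 3 that would speak against it. Both bounds were set after slopes had been seen. A bound of 5%, tried once the percentage was known, would have spoken against the span and was dropped for that reason, and the percentage went from 5.15% to 20.6% when samples were left out and was 22.7% when scaled by the deposited wild-type fold repression.

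Core and terminator stem parted as shares of the span: core minus stem was 6.43, 3.24, 6.36, 19.2, 26.1 and 23.5 percentage points from 21 °C to 37 °C replicate 2 (r = 0.91, exact permutation p = 0.028, adjusted over 3 added measures p = 0.050, rho = 0.81, exact permutation p = 0.072, adjusted p = 0.16, r 0.97 to 0.98 without the 2 farthest samples). The other level definitions (lower r = 0.9032) and leaving out any sample (lowest r = 0.8811, exact permutation p up to 0.067) argue against a single setting or sample as the source. Wider gates at 25 and 29 °C were expected to put 21 °C with the warm samples, but it lay 14.85 points nearer to 25 and 29 °C. This cannot decide against gate width. Gate 4 (upper over lower bound) was 1.58-fold wide at 21 °C, between 1.68 at 29 °C and 1.54 at 33 °C. Over the 6 samples core minus stem was lower the wider that gate, from 1.47 at 37 °C replicate 1 to 1.72 at 25 °C. Gate width and temperature thus cannot be told apart for this difference. Additive regression gave a much smaller difference that changed sign, from -3.45 at 21 °C to 5.30 and 3.28 at 37 °C, and its cause was not tested. A greater weight of pairing against RNA stability or Hfq binding at higher temperature is a possible explanation, and it was not tested.

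A31G exceeded the core-disrupted level by 0.35 and 0.27 in the samples of 37 °C and by 0.09, -0.01, -0.01 and 0.16 at 21, 25, 29 and 33 °C. A second change in its founder clone would be missing from doubles if these arose apart from it, but 38 doubles with mild partners had a median cost of 0.9457 of that of A31G. That ratio concerns the whole cost and not the excess. A31G cost 1.13 in the mean over samples, those doubles 1.07 in the median, and the span averaged 0.99. Doubles that had lost all of the excess would thus still have kept most of the cost. Counting error was smaller than the excess by 10.91 times or more at 37 °C, with at least 6355 cells in every sample. The cell numbers argue against counting error as the source of the excess at 37 °C. The doubles argue against a second change as the source of most of the A31G cost, but cannot decide on the excess. Why the level lies above that of disrupted variants stays open.

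Among 254 substitutions outside the core, cost and the predicted openness of the core had rho = -0.058 (permutation p = 0.36). Among the 83 at positions 32 to 37 and 47 to 68, where most gains lay, rho was 0.26 (permutation p = 0.019, chosen after the first result was seen). This direction is opposite to gains through a more open core in the predicted fold. The predicted wild-type fold lacks the pairs 7 with 29 and 8 with 28 that the doubles point to. The prediction therefore cannot decide whether a more open core gives the gains. The sequence CATTGCT occurs at positions 40 to 46 and again at 49 to 55, with mean costs of 0.85 and 0.01, and costs at the same place of both copies had rho = 0.18 (permutation p = 0.44), against a second copy that mirrors the first. The log2 ratio of cells between the 37 °C samples correlated with cost across substitutions (r = -0.70, rho = -0.75), with an SD of 0.32. For the other neighbouring samples, r with the mean cost was 0.56 (25 over 21 °C, SD 0.56), -0.31 (29 over 25 °C, SD 0.25), 0.26 (33 over 29 °C, SD 0.24) and -0.02 (37 °C replicate 1 over 33 °C, SD 0.19).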
